A study of Mus musculus with 335 samples.

How the data were processed

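RNA from snap-frozen tissue or cultured cells of 335 mouse samples was sequenced on a HiSeq2500 with TruSeq v4 chemistry, per the labels' protocols. Reads were aligned to mm9 with TopHat and processed with DESeq2, per the submitters' processing notes, which state no version of either. The authors deposited RPKM values (reads per kilobase of transcript, scaled to the reads of the library) for all 335 libraries in a single table. The notes do not say how DESeq2 entered these values. No reads or counts were at hand, so no count-based test was used. Of all genes, 19495 were above 0 in at least 1 library.

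Depth was recovered from the table itself. In genes of low value the RPKM of a library move in equal steps of 1 read, and 10439 genes had such steps. Over them 100% of values lay within 0.001 reads of a whole number. Each library thus gave its total of counted reads, from 8106344 to 54906212 with a median of 27175852. In a transcript of 1 kilobase 1 read equals 0.0368 RPKM at the median depth, 0.123 at the lowest and 0.0182 at the highest, so lower means rest on few reads. The same recovery on simulated libraries had a largest relative error of 0.0. Genes with steps hold 19.4% of the summed value, so the depth of the remaining genes is inferred from them. Among 1223 pairs of libraries compared, 0 were identical.

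Groups, animals and pairs were taken from the sample labels, and 61 groups resulted. Where labels of a sample conflicted, the source entry was followed for 1 Met1 and 2 MOLF primary tumours titled lung met, and the cell line entry for the 6 Mvt1 tail vein metastases, whose titles begin with Met1. The title was followed for 1 FVB tumour with a MOLF strain entry and 1 Met1 tumour titled resected. It was also followed where deposited column names give another animal number, in 2 animals of PyMT in FVB, 1 each of PyMT in BL6 and M6, and the TSAE1 tumours. Other conflicts were the route of 2 6DT1 liver libraries of 1 animal and the strain of 4 cell libraries. Libraries of the same tissue from 1 animal were averaged, so that the animal was the unit. Pairing came from the same animal named in both labels. As a check, deviations from the group means were correlated within pairs. Correlations over 0.1 were found in 4 of 6 pairs for 4T1, 4 of 6 for 6DT1, 2 of 6 for Mvt1, 4 of 6 for Met1, 4 of 6 for M6, 9 of 12 for PyMT in FVB, 2 of 5 in BL6, 2 of 6 in BL10, 6 of 7 in CAST and 7 of 8 in MOLF. They were found in 2 of 3 pairs of liver and lung metastases and in 3 of 4 pairs of resected and final tumours.

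RPKM were taken to log2(RPKM + 1). Each of 32 comparisons kept genes at RPKM of 1 or more in at least as many profiles as the smaller group held, which left 8713 to 12252 genes. Differences were fitted with limma 3.58.1 under R 4.3.3, on tables read with the data.table package at version 1.17.8, with trend and robust moderation, with the animal as a block where animals were paired. A gene was called at an adjusted p (Benjamini and Hochberg) under 0.05. Metastases and primary tumours were compared in each of 10 models. The shared comparison used 1 mean difference per model, and the interaction tests compared those differences between kinds of model, or those of animals between Met1 and PyMT in FVB. Tumours and cultured cells were compared over line means. All other comparisons were between groups of animals.

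In all, 46 gene lists written before the values were seen were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation. The share of lung RNA in a library was the median, over lists of lung epithelial genes, of its level above the primary tumour mean relative to healthy lung, bounded to 0.95. Nearest profiles used correlation over the 2000 most variable genes, with a permutation test of 100000 shuffles of the model labels. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

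Named genes came from 1 rule. They had an adjusted p under 0.05, a difference of at least 2-fold and a mean of at least 5 RPKM in the higher group. Paired designs needed the same direction in every pair or model. From these the 10 largest differences in each direction were taken for the shared comparison and 5 for the others. For metastases against tumours the largest rises among genes less than 2-fold higher in healthy lung, also on the log2(RPKM + 1) scale, were added. Up to 4 members of each called list with the smallest adjusted p, and labelled drivers, were eligible too. Predicted genes and receptor or immunoglobulin segments were left out.

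The fits were tested on simulated data of the same sizes. With 6 pairs like those of 4T1, limma recovered 76 of 100 genes changed by 1 on the log2 scale and 96 of 100 changed by 2, with 4 false calls among 11257 genes. With 3 pairs of liver and lung metastases it recovered 0 and 34, and with 4 pairs of resected and final tumours 14 and 77. A shifted list had adjusted p = 7.5e-14, and known lung shares were recovered to 0.00603 percentage points. Shares in metastases differed by lung cell type, which this does not test.

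Comparisons, tests, the rule for genes and most alternatives were fixed before the data were examined. Alternatives were a pseudocount of 0.1, no filter, rescaling of libraries to the median ratio over genes, no pairing, subtraction of the lung or liver share, single library series, other sets of models and removal of each animal in turn. Small groups left out of the tests (Neu, brain, spleen, and some routes) and the primary tumours of 7 further lines, which had no metastases or sister line in the series, are described by their levels in the closing section. Of the animals with BL6 tumours, 2 whose tumour or metastasis label had no partner were outside the paired test. Results for some genes that the rule would name are not reported here.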

Results

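The series held 335 RNA-seq libraries in 61 groups from mouse models of metastatic mammary cancer. Primary tumours gave 131 libraries, lung metastases 130, liver metastases 20, spleen metastases 5 and brain metastases 2. Cultured lines gave 24, tumour-adjacent lung 5, tumour-adjacent liver 8, tumour-adjacent spleen 2, healthy lung 4 and healthy liver 4. Gene values were the deposited RPKM, at a median of 27175852 counted reads.

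Models were of 2 kinds. In allografts a mammary tumour line was injected into mice, most often into the mammary gland (orthotopic), otherwise into the tail vein or the heart. The lines 4T1, 4T07 and 67NR are sisters from 1 mammary tumour of a BALB/c mouse. The labels gave Myc as the driver of 6DT1, Myc and VEGF for Mvt1, PyMT (polyoma middle T antigen) for Met1 and SV40 T antigen for M6. In the transgenic models the tumours arose in the animal. They carried MMTV-PyMT in mice labelled FVB, BL6, BL10, CAST or MOLF, or else MMTV-Myc, MMTV-Neu or C3Tag (SV40 T antigen). Each fold below is a difference on the log2(RPKM + 1) scale with its standard error, which understates low genes, and the levels are group means. For a gene list, the first adjusted p came from camera with a preset correlation between genes.

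Lung metastases of 10 models shared lung-cell RNA, neutrophil RNA and a loss of fibroblast matrix RNA when set against the primary tumours of the same 68 animals. Surfactant genes of alveolar type 2 cells rose: Sftpc (10.02 ± 0.26, 2842 against 1.45 RPKM), Sftpb (6.86 ± 0.14, 235 against 0.125 RPKM), Sftpa1 (6.83 ± 0.18, 242 against 0.105 RPKM) and Sftpd (5.33 ± 0.42, 125 against 1.77 RPKM). Type 1 cells were represented by Ager (5.33 ± 0.14, 94.6 against 0.959 RPKM), and club cells of the airway by Scgb1a1 (7.08 ± 0.26, 868 against 0.533 RPKM). Of 9 alveolar type 2 genes 9 were higher, 0 lower and 0 not called (9 higher adjusted over the list alone, adjusted p = 5.44e-18, adjusted p = 0.0727 with an estimated correlation). The 6 alveolar type 1 genes split into 5 higher, 0 lower and 1 not called (5 higher adjusted over the list alone, adjusted p = 6.09e-10, adjusted p = 0.101 with an estimated correlation). Among 4 club cell genes 4 were higher, 0 lower and 0 not called (4 higher adjusted over the list alone, adjusted p = 4.35e-08, adjusted p = 0.0727 with an estimated correlation). Lung RNA was estimated from such genes at a mean of 18 ± 4.73% in 6DT1, 15.8 ± 9.82% in 4T1, 7.54 ± 3.96% in CAST and 6.27 ± 3.17% in MOLF metastases.

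**Figure D1:**
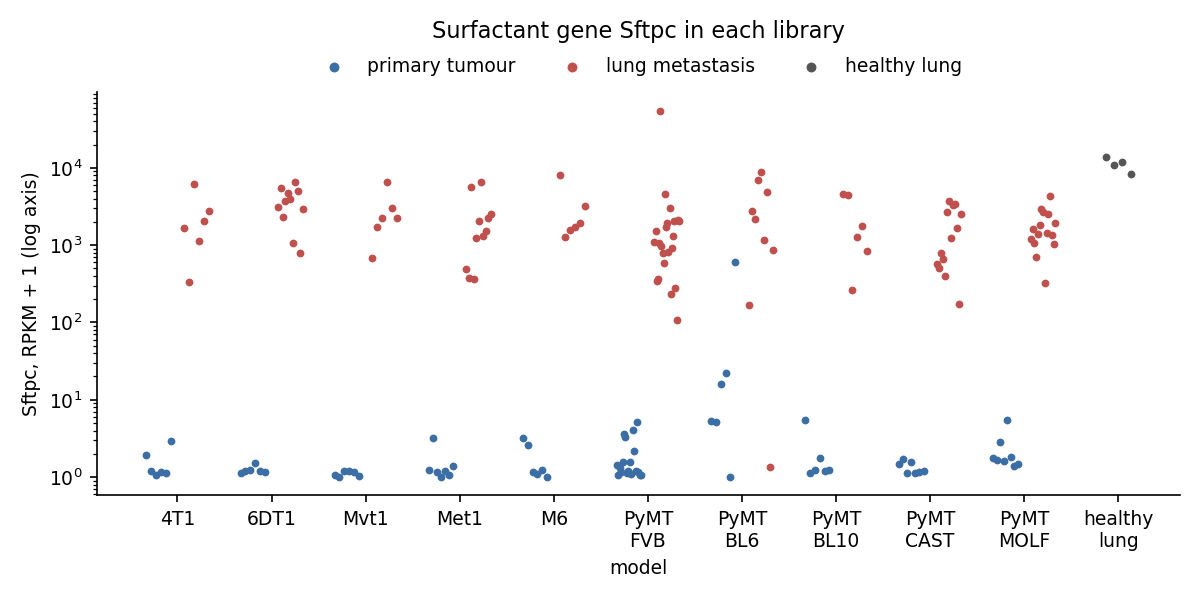
Sftpc level in each library of primary tumours, lung metastases and lung without tumour, by model. Sftpc encodes surfactant protein C, made by alveolar type 2 cells.

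**Figure D2:**
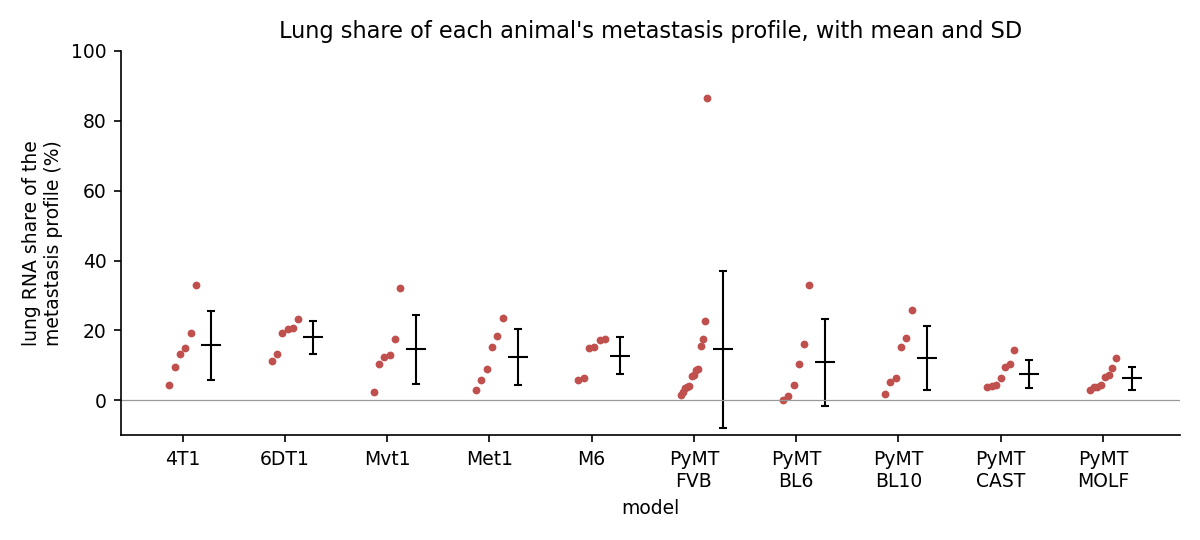
Estimated share of lung RNA in each animal's lung metastases, by model, with the mean and standard deviation.

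Genes less than 2-fold higher in healthy lung than in the primary tumour mean over models, on the scale of log2(RPKM + 1), included neutrophil products. S100a9 and S100a8 encode the 2 chains of calprotectin: S100a9 (3.33 ± 0.29, 522.1 against 74.6 RPKM) and S100a8 (2.29 ± 0.27, 458 against 98.9 RPKM). The tumour mean of S100a9 was raised by 4T1 (292 RPKM) and MOLF (271). Tumours of the other models averaged 4.40 (BL10) to 63.5 (Mvt1), below the 139 of healthy lung. Beside them stood Retnlg (3.23 ± 0.18), Ngp (2.52 ± 0.23), Mmp8 (1.40 ± 0.12), Csf3r (1.30 ± 0.09) and Stfa2l1 (1.5 ± 0.17). Of 9 neutrophil genes 8 were higher, 0 lower and 1 not called (8 higher adjusted over the list alone, adjusted p = 1.12e-10, adjusted p = 0.0727 with an estimated correlation). Gpnmb (2.25 ± 0.28, 0.118 to 146 RPKM in cultured lines), Ifitm6 (1.87 ± 0.17) and Alox5ap (1.23 ± 0.08) rose as well.

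The 12 endothelial genes split into 12 higher, 0 lower and 0 not called (12 higher adjusted over the list alone, adjusted p = 4.33e-11, adjusted p = 0.214 with an estimated correlation). Tek (1.10 ± 0.09), Ramp2 (1.94 ± 0.16) and Esam (1.20 ± 0.10) were examples, but Ramp2 (-1.66) and Esam (-0.87) had the opposite sign once the estimated lung share was subtracted. Among 18 cholesterol synthesis genes 13 were higher, 1 lower and 4 not called (13 higher and 1 lower adjusted over the list alone, adjusted p = 6.13e-06, adjusted p = 0.375 with an estimated correlation), with Fdps (0.59 ± 0.09), Stard4 (0.35 ± 0.06) and Nsdhl (0.36 ± 0.08). Of 7 MHC class II genes 5 were higher, 0 lower and 2 not called (7 higher adjusted over the list alone, adjusted p = 0.00103, adjusted p = 0.468 with an estimated correlation), with H2-Ab1 (0.83 ± 0.20) and H2-DMa (0.61 ± 0.15). The 9 inflammation genes split into 5 higher, 0 lower and 4 not called (5 higher adjusted over the list alone, adjusted p = 0.00378, adjusted p = 0.359 with an estimated correlation), with Icam1 (2.06 ± 0.16) and Il1b (0.75 ± 0.13).

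Matrix genes of fibroblasts fell. Lum (-2.81 ± 0.19), Col1a1 (-2.40 ± 0.15), Thbs2 (-2.37 ± 0.21), Postn (-2.11 ± 0.23), Col12a1 (-2.02 ± 0.18), Col1a2 (-2.0 ± 0.16) and Col8a1 (-1.65 ± 0.12) had the largest declines, with Serpinf1 (-2.0 ± 0.19), Mmp3 (-1.83 ± 0.13) and Ccl8 (-2.23 ± 0.31). Among 20 fibroblast matrix genes 1 was higher, 16 lower and 3 not called (16 lower and 1 higher adjusted over the list alone, adjusted p = 4.35e-08, adjusted p = 0.218 with an estimated correlation). Of 19 hypoxia and glycolysis genes 0 were higher, 8 lower and 11 not called (8 lower adjusted over the list alone, adjusted p = 0.0453, adjusted p = 0.747 with an estimated correlation), with Pfkl (-0.45 ± 0.06), Egln3 (-0.67 ± 0.10) and Pdk1 (-0.52 ± 0.11).

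With 1 mean difference per model, limma called 3411 of 11089 genes, 1235 higher (157 at least 2-fold) and 2176 lower (37), the genes named here with adjusted p up to 0.0111. Rescaled to the median ratio of the libraries, 1578 were higher and 1577 lower. Of called genes 528 were higher and 835 lower with the same sign in all 10 models, 142 and 33 of them at least 2-fold. Of the 528, 275 were at least 2-fold higher in healthy lung than in primary tumours and 253 (19 of the 142) were not. Tested in each model alone, Sftpc, Sftpb, Sftpa1, Sftpd, Cxcl15, Ager, Cldn18, Lamp3, Sec14l3 and Sfta2 were called higher in all 10. No gene was called lower in all 10 (Col12a1 was in 9).

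Metastases of 4T1, a line without a labelled driver, carried granule genes of neutrophils. Ngp (3.51 ± 0.56, 142 against 8.62 RPKM), Camp (3.15 ± 0.52, 38.2 against 2.24 RPKM) and Ltf (2.96 ± 0.50) rose, as did Ifitm6 (2.87 ± 0.55) and Rprl1 (3.24 ± 0.58). The 10 neutrophil genes split into 3 higher, 0 lower and 7 not called (6 higher adjusted over the list alone, adjusted p = 0.00146, adjusted p = 0.611 with an estimated correlation). The primary tumours held more Crabp1 (-3.42 ± 0.47), Lrrc15 (-3.88 ± 0.28) and Gzmd (-3.74 ± 0.55), the last a granzyme whose paralogs share reads. Among 19 hypoxia and glycolysis genes 0 were higher, 5 lower and 14 not called (10 lower adjusted over the list alone, adjusted p = 6.37e-06, adjusted p = 0.604 with an estimated correlation), with Bnip3 (-1.55 ± 0.21) and Slc2a1 (-1.25 ± 0.21). Of 21 fibroblast matrix genes 0 were higher, 6 lower and 15 not called (8 lower adjusted over the list alone, adjusted p = 2.12e-04, adjusted p = 0.611 with an estimated correlation), with Col12a1 (-3.02 ± 0.39) and Postn (-2.77 ± 0.41). Lung RNA was estimated at 15.8 ± 9.82%. In 6 pairs limma called 1363 of 11257 genes, 828 higher (304 at least 2-fold) and 535 lower (111), the genes named here with adjusted p up to 0.0185. After rescaling, 739 were higher and 932 lower.

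In 6DT1, driven by Myc, metastases gained the cytokine Il24 (3.86 ± 0.24, 94.2 against 5.59 RPKM), the plasminogen activator inhibitor Serpinb2 (3.37 ± 0.19, 28.5 against 1.80 RPKM) and the acute-phase gene Saa3 (3.10 ± 0.42). Prl2c3 (5.24 ± 0.32) rose too, with the reservation that Prl2c paralogs share reads. The 11 epithelial genes split into 8 higher, 0 lower and 3 not called (10 higher and 1 lower adjusted over the list alone, adjusted p = 4.10e-06, adjusted p = 0.259 with an estimated correlation), with Krt7 (4.83 ± 0.17), Cldn3 (3.38 ± 0.13) and Cdh1 (2.52 ± 0.12). In healthy lung Krt7 was at 132, Cldn3 at 56.2 and Cdh1 at 48.7 RPKM. With the lung share subtracted Krt7 stayed called (3.18, adjusted p = 0.0012), while Cldn3 and Cdh1 no longer passed the filter. Among 22 interferon-stimulated genes 16 were higher, 1 lower and 5 not called (19 higher and 1 lower adjusted over the list alone, adjusted p = 2.85e-05, adjusted p = 0.368 with an estimated correlation), with Ifit3 (1.60 ± 0.26) and Oasl1 (0.56 ± 0.10). Of 9 NRF2 target genes 8 were higher, 0 lower and 1 not called (8 higher adjusted over the list alone, adjusted p = 0.00148, adjusted p = 0.259 with an estimated correlation), with Me1 (1.18 ± 0.12) and Gclc (1.47 ± 0.21). NRF2 controls genes against oxidative stress. Lower in metastases were Thbs2 (-3.09 ± 0.27), Postn (-3.20 ± 0.20), Crabp1 (-4.36 ± 0.18) and 2 proteases of mast cells, Tpsb2 (-3.40 ± 0.39) and Mcpt4 (-3.45 ± 0.24). The 12 ribosomal protein genes split into 0 higher, 12 lower and 0 not called (12 lower adjusted over the list alone, adjusted p = 3.02e-08, adjusted p = 0.359 with an estimated correlation), with Rpl3 (-0.84 ± 0.09) and Rps14 (-0.96 ± 0.10). The lung estimate averaged 18 ± 4.73%. Over 6 pairs limma called 3828 of 11121 genes, 2162 higher (440 at least 2-fold) and 1666 lower (143), the genes named here with adjusted p up to 0.00376.

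Mvt1 metastases had more Gpnmb (2.76 ± 0.53, 17.5 against 2.23 RPKM), Serpina3n (2.42 ± 0.43, 74.2 against 24.8 RPKM), Lrg1 (1.93 ± 0.37), Serpinb7 (1.97 ± 0.53) and Fbp2 (1.76 ± 0.44). Serpina3n and Lrg1 encode secreted acute-phase proteins. Matrix genes fell: Postn (-3.39 ± 0.33), Thbs2 (-3.14 ± 0.46), Col12a1 (-2.68 ± 0.29) and Lrrc15 (-2.95 ± 0.41), as did Crabp1 (-4.34 ± 0.49). Among 20 fibroblast matrix genes 0 were higher, 11 lower and 9 not called (15 lower and 1 higher adjusted over the list alone, adjusted p = 0.00258, adjusted p = 0.696 with an estimated correlation), with Thy1 (-1.71 ± 0.21) and Col6a2 (-1.52 ± 0.27). A lung share of 14.7 ± 9.86% was estimated. Myc was at 35.69 RPKM in the lowest primary tumour (mean 327.4). From 6 pairs limma called 3172 of 10940 genes, 1228 higher (188 at least 2-fold) and 1944 lower (131), the genes named here with adjusted p up to 0.0299.

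Metastases of Met1, a PyMT line, showed few single-gene differences. Beyond surfactant genes, the lectin gene Cd209c (2.12 ± 0.28, 72.5 against 14.6 RPKM) rose, and Postn (-2.20 ± 0.28, 18.3 against 82.9 RPKM), Col12a1 (-2.0 ± 0.22), Fxyd2 (-2.59 ± 0.36) and H19 (-2.77 ± 0.36) fell. H19 is an imprinted RNA. Of 20 fibroblast matrix genes 0 were higher, 2 lower and 18 not called (10 lower adjusted over the list alone, adjusted p = 1.80e-10, adjusted p = 0.448 with an estimated correlation), with Col1a1 (-2.78 ± 0.44, adjusted p = 0.0731) and Col1a2 (-2.42 ± 0.52, adjusted p = 0.193). The 10 neutrophil genes split into 0 higher, 0 lower and 10 not called (9 higher adjusted over the list alone, adjusted p = 1.86e-11, adjusted p = 0.268 with an estimated correlation), with S100a9 (4.21 ± 0.76, adjusted p = 0.109) and Retnlg (4.06 ± 0.76, adjusted p = 0.122). The lung estimate came to 12.4 ± 7.93%. For 6 pairs limma called 35 genes (57 without pairing), 29 higher (29 at least 2-fold) and 6 lower (6), the genes named here with adjusted p up to 0.0432.

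In M6, a line driven by SV40 T antigen, metastases gained macrophage and T cell genes. Mmp12 (1.98 ± 0.38, 29.1 against 10.6 RPKM), the elastase of macrophages, Cd68 (1.61 ± 0.31, 63.0 against 18.5 RPKM) and the interferon-gamma induced chemokine Cxcl9 (1.96 ± 0.41) rose, as did Eln (1.86 ± 0.35), which encodes elastin. Among 6 T and NK cell genes 5 were higher, 0 lower and 1 not called (5 higher adjusted over the list alone, adjusted p = 2.38e-06, adjusted p = 0.234 with an estimated correlation), with Cd3d (1.95 ± 0.23) and Cd4 (1.58 ± 0.21). Col1a1 (-2.72 ± 0.28), Lum (-2.75 ± 0.46), Thbs2 (-3.48 ± 0.35), Lrrc15 (-3.56 ± 0.36) and Crabp1 (-3.03 ± 0.59) fell. Of 20 fibroblast matrix genes 0 were higher, 6 lower and 14 not called (14 lower adjusted over the list alone, adjusted p = 4.15e-08, adjusted p = 0.234 with an estimated correlation). Lung RNA averaged 12.8 ± 5.32% by the estimate. Across 6 pairs limma called 529 of 11228 genes, 410 higher (293 at least 2-fold) and 119 lower (32), the genes named here with adjusted p up to 0.037. Rescaled, 345 were higher and 232 lower.

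Metastases of PyMT in FVB gained Gpnmb (1.37 ± 0.30, 8.1 against 2.27 RPKM) and lost Lum (-2.90 ± 0.44, 0.645 against 15.8 RPKM). The 10 endothelial genes split into 4 higher, 0 lower and 6 not called (9 higher adjusted over the list alone, adjusted p = 8.62e-15, adjusted p = 0.0973 with an estimated correlation), with Cldn5 (1.84 ± 0.29) and Ramp2 (1.66 ± 0.28). Among 9 alveolar type 2 genes 8 were higher, 0 lower and 1 not called (8 higher adjusted over the list alone, adjusted p = 2.03e-27, adjusted p = 0.0194 with an estimated correlation), with Sftpc (9.50 ± 0.53) and Sftpb (6.91 ± 0.55). The lung estimate was 14.6 ± 22.6% (median 7.15%, 86.6% in mouse9716). Unlike a lung mixture, its metastasis had Sftpc at 55030, Ager at 356 and Scgb1a1 at 627.7 RPKM (11210, 951.6 and 49070 in healthy lung). The milk gene Csn3 was 1.202 in 1 animal (mean 7818), so its label is in doubt. In 12 pairs limma called 141 of 11075 genes (224 without pairing), 94 higher (73 at least 2-fold) and 47 lower (4), the genes named here with adjusted p up to 0.040. Rescaled, 97 were higher and 15 lower.

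BL6 animals with PyMT lost collagen and matrix genes in the metastases: Col1a1 (-2.49 ± 0.24, 3.58 against 24.1 RPKM), Lum (-3.57 ± 0.22, 0.721 against 20.5 RPKM), Lrrc15 (-2.59 ± 0.19), Cilp (-2.74 ± 0.22) and C1qtnf3 (-2.96 ± 0.23). Of 20 fibroblast matrix genes 0 were higher, 5 lower and 15 not called (11 lower and 1 higher adjusted over the list alone, adjusted p = 3.70e-07, adjusted p = 0.514 with an estimated correlation). The 7 neutrophil genes split into 0 higher, 0 lower and 7 not called (6 higher adjusted over the list alone, adjusted p = 1.32e-08, adjusted p = 0.303 with an estimated correlation), with S100a9 (4.34 ± 0.73, adjusted p = 0.0621) and Ngp (2.82 ± 0.62, adjusted p = 0.121). The RNase P component Rpph1 (1.76 ± 0.27) rose. Lung RNA was put at 10.8 ± 12.4% over 6 animals, among them mouse9783 at 0, which was outside the pairs. In 5 pairs limma called 73 of 11214 genes (65 without pairing), 44 higher (44 at least 2-fold) and 29 lower (28), the genes named here with adjusted p up to 0.0271.

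Metastases in BL10 animals gained Mmp12 (3.05 ± 0.54, 36.2 against 1.86 RPKM), Gpnmb (2.36 ± 0.39, 18.9 against 2.37 RPKM), B2m (1.39 ± 0.20) and Lao1 (1.32 ± 0.27). B2m is the invariant chain of MHC class I. Among 11 endothelial genes 3 were higher, 0 lower and 8 not called (11 higher adjusted over the list alone, adjusted p = 1.44e-10, adjusted p = 0.382 with an estimated correlation), with Cldn5 (2.97 ± 0.50) and Flt1 (1.32 ± 0.25). Lum (-3.38 ± 0.40) fell, as did major urinary protein genes such as Mup19 (-2.67 ± 0.36), whose near-identical copies leave the gene uncertain. Of 3 hepatocyte genes 0 were higher, 2 lower and 1 not called (2 lower adjusted over the list alone, adjusted p = 0.0148, adjusted p = 0.382 with an estimated correlation), with Fgb (-2.21 ± 0.34) and Fgg (-1.72 ± 0.36). The estimate of lung RNA was 12.1 ± 9.21%. With 6 pairs limma called 287 of 11208 genes (545 without pairing), 109 higher (81 at least 2-fold) and 178 lower (90), the genes named here with adjusted p up to 0.0499.

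CAST metastases were low in matrix genes. Col1a1 (-3.13 ± 0.33, 2.65 against 32.2 RPKM), Lum (-3.10 ± 0.23, 0.724 against 15.6 RPKM), the collagenase Mmp13 (-3.08 ± 0.52), Amtn (-3.17 ± 0.47) and the chemokine Ccl8 (-3.21 ± 0.41) fell. The 21 fibroblast matrix genes split into 0 higher, 15 lower and 6 not called (18 lower adjusted over the list alone, adjusted p = 2.39e-15, adjusted p = 0.316 with an estimated correlation), with Col12a1 (-2.22 ± 0.21) and Col5a2 (-1.69 ± 0.17). Gpnmb (2.30 ± 0.39) rose. Among 10 neutrophil genes 6 were higher, 0 lower and 4 not called (7 higher adjusted over the list alone, adjusted p = 1.08e-10, adjusted p = 0.287 with an estimated correlation), with S100a9 (3.81 ± 0.39) and Retnlg (3.52 ± 0.40). Lung RNA was estimated as 7.54 ± 3.96%. By 7 pairs limma called 505 of 11185 genes, 147 higher (92 at least 2-fold) and 358 lower (105), the genes named here with adjusted p up to 0.0168. After rescaling, 168 were higher and 185 lower.

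Neutrophil genes rose in MOLF metastases: S100a9 (3.46 ± 0.68, 1715 against 271 RPKM), Ngp (3.46 ± 0.62, 93.9 against 6.25 RPKM), Retnlg (3.42 ± 0.67) and Camp (3.29 ± 0.51). Of 10 neutrophil genes 5 were higher, 0 lower and 5 not called (8 higher adjusted over the list alone, adjusted p = 8.87e-18, adjusted p = 0.104 with an estimated correlation). The kallikrein Klk10 (2.37 ± 0.33) also rose. Col3a1 (-2.88 ± 0.44), Col1a1 (-2.88 ± 0.42), Dcn (-3.05 ± 0.40), Lum (-3.52 ± 0.31) and Ccl8 (-3.40 ± 0.25) fell. The 21 fibroblast matrix genes split into 0 higher, 11 lower and 10 not called (16 lower adjusted over the list alone, adjusted p = 3.75e-21, adjusted p = 0.198 with an estimated correlation). Among 9 alveolar type 2 genes 7 were higher, 0 lower and 2 not called (8 higher adjusted over the list alone, adjusted p = 1.79e-40, adjusted p = 0.00575 with an estimated correlation). The lung share estimate was 6.27 ± 3.17%. On 8 pairs limma called 121 of 11033 genes, 68 higher (55 at least 2-fold) and 53 lower (38), the genes named here with adjusted p up to 0.0469.

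The difference between metastasis and primary tumour was compared between the 5 injected lines and the 5 transgenic PyMT models. Of the injected lines only Met1 was labelled PyMT, so kind of model, driver and line were confounded. It was larger in the injected lines for Slc34a2 (5.23 in allografts against 2.22 in transgenic models, difference 3.0 ± 0.39), a phosphate transporter of type 2 cells, Muc1 (3.36 against 0.84, difference 2.52 ± 0.35), Sftpd (6.54 against 4.12, difference 2.42 ± 0.48), Slpi (1.59 against -0.24, difference 1.83 ± 0.32), Wfdc12 (0.59 against -1.58, difference 2.18 ± 0.29) and Lrg1 (1.68 against -0.14, difference 1.82 ± 0.30). Smooth-muscle actin went the other way, Acta2 (-0.62 against 0.54, difference -1.16 ± 0.23), with Rbp7 (-0.50 against 0.84, difference -1.34 ± 0.20). Of 15 epithelial genes 1 was higher, 0 lower and 14 not called (4 higher adjusted over the list alone, adjusted p = 5.99e-04, adjusted p = 0.662 with an estimated correlation), with Ehf (1.17 ± 0.16) and Cldn3 (1.83 ± 0.49, adjusted p = 0.132). As an interaction between 5 and 5 models, limma called 76 of 12227 genes, 68 higher (32 at least 2-fold) and 8 lower (2), the genes named here with adjusted p up to 0.0489. With the lung share subtracted 17 were called, and rescaled 35 were higher and 7 lower.

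Met1 allografts and transgenic PyMT in FVB mice share driver and strain, and for no gene was the metastasis difference called unequal. Values for Fos (1.12 ± 0.26, adjusted p = 0.644), an immediate early gene, and Krt19 (1.79 ± 0.61, adjusted p = 0.806) were higher in Met1 by the fold shown. The 11 immediate early genes split into 0 higher, 0 lower and 11 not called (6 higher adjusted over the list alone, adjusted p = 1.03e-07, adjusted p = 0.139 with an estimated correlation). Among 7 MHC class II genes 0 were higher, 0 lower and 7 not called (0 lower adjusted over the list alone, adjusted p = 2.24e-06, adjusted p = 0.313 with an estimated correlation), with Cd74 (-2.04 ± 0.72, adjusted p = 0.806). As an interaction of 6 with 12 pairs, limma called 0 of 12191 genes, with 686 at an unadjusted p under 0.05 where 610 were expected by chance.

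Nearest profiles were mostly of the same model. Each of 70 animals with lung metastases was matched to the closest profile of another animal among lung metastases and primary tumours, by correlation over the 2000 most variable genes. The partner came from the same model for 54 animals (77.1%, against 10% by chance), and from a model with the same driver for 68 (97.1%, against 47.6%). All animals of 4T1, 6DT1, Met1 and M6 matched their own model, 4 of 6 for Mvt1, 10 of 13 for PyMT in FVB, 3 of 6 in BL6, 2 of 6 in BL10, 4 of 7 in CAST and 7 of 8 in MOLF. The partner was a lung metastasis for 63 of 70. A permutation test of the model labels gave p = 1e-05 for both shares, the smallest it can give. Library series and host strain went partly with model and were not held fixed in it.

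The route of injection went with immune genes in 4T1 lung metastases. After tail vein injection Ccl8 (-2.20 ± 0.57, 7.39 against 39.0 RPKM), the ubiquitin-like Ubd (-2.20 ± 0.47, 2.06 against 11.9 RPKM), Camp (-2.27 ± 0.60), Ltf (-2.36 ± 0.58) and Retnla (-4.85 ± 1.14) were lower than after injection into the mammary gland. Of 22 interferon-stimulated genes 0 were higher, 6 lower and 16 not called (19 lower adjusted over the list alone, adjusted p = 6.50e-11, adjusted p = 0.519 with an estimated correlation), with Ddx58 (-0.74 ± 0.17) and Stat2 (-1.15 ± 0.27). The 11 T and NK cell genes split into 0 higher, 7 lower and 4 not called (11 lower adjusted over the list alone, adjusted p = 1.69e-08, adjusted p = 0.519 with an estimated correlation), with Lck (-1.34 ± 0.26) and Gzmb (-1.28 ± 0.28). Cd209c (2.58 ± 0.68), Mmp3 (1.92 ± 0.51), Msln (1.77 ± 0.42) and Macc1 (1.49 ± 0.29) were higher. Among 9 alveolar type 2 genes 0 were higher, 1 lower and 8 not called (7 lower adjusted over the list alone, adjusted p = 1.00e-04, adjusted p = 0.519 with an estimated correlation), with Lyz1 (-2.12 ± 0.58) and Napsa (-0.95 ± 0.33, adjusted p = 0.0999). With 6 against 6 animals limma called 649 of 11285 genes, 437 higher (19 at least 2-fold) and 212 lower (57), the genes named here with adjusted p up to 0.0486.

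In Mvt1 the same contrast was mostly of small folds. Snhg3 (1.44 ± 0.19, 61.9 against 22.8 RPKM), a host gene of small nucleolar RNA, and Atg9b (1.17 ± 0.15, 16.3 against 6.70 RPKM) were higher after tail vein injection. Of 10 MHC class I genes 0 were higher, 6 lower and 4 not called (8 lower adjusted over the list alone, adjusted p = 1.35e-13, adjusted p = 0.195 with an estimated correlation), with Psmb8 (-0.92 ± 0.18), B2m (-0.58 ± 0.11) and Tap2 (-0.73 ± 0.14). Between 6 and 6 animals limma called 470 of 11068 genes, 441 higher (28 at least 2-fold) and 29 lower (2), the genes named here with adjusted p up to 0.019. Rescaled, 105 were higher and 55 lower.

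For 6DT1, milk protein genes were higher after tail vein injection: Wap (3.35 ± 0.61, 16.1 against 0.324 RPKM) and Csn1s2a (2.32 ± 0.45, 6.07 against 0.0939 RPKM), with Sncg (2.49 ± 0.60), Orm1 (2.36 ± 0.47) and Kcnt1 (2.43 ± 0.33). The 6 milk protein genes split into 4 higher, 0 lower and 2 not called (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.00404, adjusted p = 0.554 with an estimated correlation). Lower were Cd74 (-2.20 ± 0.42), the invariant chain of MHC class II, Cxcl9 (-3.21 ± 0.80), Cxcl11 (-2.42 ± 0.67), Il24 (-2.72 ± 0.45) and Ly6i (-3.12 ± 0.61). Among 15 T and NK cell genes 0 were higher, 7 lower and 8 not called (11 lower adjusted over the list alone, adjusted p = 1.31e-04, adjusted p = 0.555 with an estimated correlation), with Cd8a (-1.36 ± 0.27) and Cd3e (-1.21 ± 0.24). Only 2 animals stood against 6, from which limma called 1187 of 11643 genes, 486 higher (116 at least 2-fold) and 701 lower (159), the genes named here with adjusted p up to 0.0496. After rescaling, 797 were higher and 508 lower.

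Primary tumours driven by Myc held more Myc (4.68 ± 0.25, 560 against 20.2 RPKM) than PyMT tumours of the same strain, with Lgals7 (3.05 ± 0.62, 291 against 42.5 RPKM), Ccnb1ip1 (3.23 ± 0.37) and Zfp575 (4.71 ± 0.27). Of 12 ribosomal protein genes 12 were higher, 0 lower and 0 not called (12 higher adjusted over the list alone, adjusted p = 5.41e-08, adjusted p = 0.897 with an estimated correlation), with Rpl10a (1.14 ± 0.13), Rpl3 (1.10 ± 0.13) and Rplp0 (0.94 ± 0.11). The 21 interferon-stimulated genes split into 0 higher, 20 lower and 1 not called (20 lower adjusted over the list alone, adjusted p = 0.00213, adjusted p = 0.897 with an estimated correlation), with Ifih1 (-1.77 ± 0.24), Ddx58 (-1.86 ± 0.26) and Stat2 (-1.81 ± 0.27). The milk gene Lalba (-5.25 ± 0.88), Igfbp5 (-5.10 ± 0.53), Clic6 (-4.77 ± 0.46), Foxi1 (-4.32 ± 0.48) and Lao1 (-4.63 ± 0.88) were lower too. With 6 against 14 animals limma called 7132 of 11521 genes, 2396 higher (699 at least 2-fold) and 4736 lower (1440), the genes named here with adjusted p up to 2.60e-04. After rescaling, 3464 were higher and 3519 lower, and the median over all genes moved from -0.21 to -0.02.

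C3Tag tumours, driven by SV40 T antigen, had far more Cdkn2a (6.18 ± 0.61, 274 against 4.34 RPKM), the p16 and p19 tumour suppressor locus, than PyMT tumours. Prkg2 (4.86 ± 0.16, 34.7 against 0.183 RPKM), Emb (4.46 ± 0.34), Msln (4.34 ± 0.27) and Amy1 (4.70 ± 1.79) were higher too. Among 14 S phase genes 13 were higher, 0 lower and 1 not called (13 higher adjusted over the list alone, adjusted p = 1.25e-04, adjusted p = 0.88 with an estimated correlation), with E2f1 (2.71 ± 0.27), Mcm3 (2.82 ± 0.35) and Mcm7 (2.23 ± 0.30). Milk and acute-phase genes were low: Wap (-6.14 ± 0.65), Csn3 (-8.49 ± 0.65), Lalba (-7.52 ± 1.03), Saa1 (-7.42 ± 0.81) and Saa2 (-7.20 ± 0.86). Of 9 milk protein genes 0 were higher, 7 lower and 2 not called (9 lower adjusted over the list alone, adjusted p = 1.20e-05, adjusted p = 0.421 with an estimated correlation). From 3 against 14 animals limma called 6017 of 12252 genes, 4008 higher (1678 at least 2-fold) and 2009 lower (704), the genes named here with adjusted p up to 0.0374. Rescaled, 2718 were higher and 3112 lower, and the median over all genes moved from 0.18 to -0.04. No C3Tag library shared a series with PyMT tumours in FVB, so series and driver were confounded.

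Set against transgenic PyMT tumours, Met1 tumours held more antigen presentation RNA and less milk RNA. The 10 MHC class I genes split into 10 higher, 0 lower and 0 not called (10 higher adjusted over the list alone, adjusted p = 2.83e-10, adjusted p = 0.48 with an estimated correlation), with Nlrc5 (2.12 ± 0.19) and B2m (2.60 ± 0.27). Cdkn2a (5.15 ± 0.45, 146 against 4.34 RPKM), Capn6 (3.67 ± 0.29, 20.8 against 0.966 RPKM) and the interferon-induced GTPase gene Tgtp2 (3.08 ± 0.44) were higher. Among 9 milk protein genes 0 were higher, 8 lower and 1 not called (8 lower adjusted over the list alone, adjusted p = 3.23e-04, adjusted p = 0.58 with an estimated correlation). Lalba (-5.84 ± 0.69), Ltf (-5.49 ± 0.67), Saa1 (-7.39 ± 0.57), Saa2 (-6.96 ± 0.62) and Clic6 (-5.45 ± 0.38) were lower. In 7 against 14 animals limma called 3528 of 11453 genes, 1370 higher (362 at least 2-fold) and 2158 lower (496), the genes named here with adjusted p up to 2.65e-05.

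Among the 3 sister lines, keratin and adhesion genes of epithelium separated 4T1 tumours from 67NR tumours. Krt8 (7.42 ± 0.22, 292 against 0.685 RPKM), Krt18 (8.21 ± 0.26, 414 against 0.427 RPKM), Krt7 (6.46 ± 0.26), Cldn4 (6.24 ± 0.41) and Wfdc2 (8.29 ± 0.10) were higher in 4T1. Of 10 epithelial genes 10 were higher, 0 lower and 0 not called (10 higher adjusted over the list alone, adjusted p = 1.21e-06, adjusted p = 0.475 with an estimated correlation). Mesenchymal regulators and adhesion genes were higher in 67NR. The 10 mesenchymal genes split into 0 higher, 8 lower and 2 not called (8 lower adjusted over the list alone, adjusted p = 0.00139, adjusted p = 0.40 with an estimated correlation), with Cdh2 (-4.19 ± 0.10), Zeb1 (-2.14 ± 0.12) and Prrx1 (-2.17 ± 0.19). Among 18 mitosis genes 0 were higher, 16 lower and 2 not called (16 lower adjusted over the list alone, adjusted p = 0.00132, adjusted p = 0.801 with an estimated correlation), with Plk1 (-1.10 ± 0.18) and Mki67 (-1.61 ± 0.26). Cox7b2 (-6.43 ± 0.12), Pnma5 (-5.86 ± 0.10), Luzp4 (-4.90 ± 0.15), Ott (-6.90 ± 0.15) and Gstt1 (-4.95 ± 0.22) were among the genes lowest in 4T1. Testing 6 against 6 animals, limma called 6672 of 11223 genes, 3316 higher (1075 at least 2-fold) and 3356 lower (922), the genes named here with adjusted p up to 1.22e-04.

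Tumours of 4T07 also exceeded 67NR in Krt8 (6.54 ± 0.17, 153 against 0.685 RPKM), Wfdc2 (7.53 ± 0.11, 197 against 0.0681 RPKM), Lgals7 (7.78 ± 0.12), Slpi (6.97 ± 0.59) and the cytokine Tslp (7.32 ± 0.38). Of 22 interferon-stimulated genes 19 were higher, 0 lower and 3 not called (19 higher adjusted over the list alone, adjusted p = 6.69e-07, adjusted p = 0.634 with an estimated correlation), with Bst2 (1.82 ± 0.11) and Ifit1 (2.10 ± 0.15). The 10 mesenchymal genes split into 1 higher, 8 lower and 1 not called (8 lower and 1 higher adjusted over the list alone, adjusted p = 0.00162, adjusted p = 0.433 with an estimated correlation), with Cdh2 (-4.47 ± 0.09) and Zeb1 (-3.10 ± 0.13). The growth factor Ereg (-4.99 ± 0.25), Pdpn (-5.78 ± 0.36), Lyz1 (-5.29 ± 0.59), Pnma5 (-5.85 ± 0.09) and Cox7b2 (-6.21 ± 0.21) were lower. For 6 against 6 animals limma called 7181 of 11090 genes, 3268 higher (937 at least 2-fold) and 3913 lower (919), the genes named here with adjusted p up to 6.70e-06.

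Directly compared, 4T1 exceeded 4T07 in Epcam (5.11 ± 0.38, 73.1 against 0.781 RPKM), Krt7 (6.33 ± 0.26, 113 against 0.312 RPKM), Cldn4 (6.03 ± 0.42), H19 (5.18 ± 0.67) and Tmprss11e (4.64 ± 0.17). Among 11 epithelial genes 10 were higher, 0 lower and 1 not called (11 higher adjusted over the list alone, adjusted p = 1.44e-06, adjusted p = 0.851 with an estimated correlation). Of 11 endothelial genes 11 were higher, 0 lower and 0 not called (11 higher adjusted over the list alone, adjusted p = 4.25e-04, adjusted p = 0.851 with an estimated correlation), with Emcn (1.93 ± 0.27) and Egfl7 (1.81 ± 0.29). Lgals7 (-5.65 ± 0.15), Sncg (-5.10 ± 0.28), Esm1 (-4.46 ± 0.47) and Bglap2 (-4.50 ± 0.23) were lower in 4T1. On 6 against 6 animals limma called 4792 of 11024 genes, 2746 higher (585 at least 2-fold) and 2046 lower (464), the genes named here with adjusted p up to 2.75e-04.

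PyMT tumours of other strains were set against those of FVB. In BL6, H2-Aa (3.19 ± 0.56, 69.5 against 10.2 RPKM) and H2-Ab1 (2.25 ± 0.50, 37.4 against 9.34 RPKM) of MHC class II were higher, with H2-Eb1 (4.2 ± 0.17), uncertain because its alleles differ between strains, and Lgals7 (2.05 ± 0.57). The 7 MHC class II genes split into 3 higher, 0 lower and 4 not called (3 higher adjusted over the list alone, adjusted p = 1.66e-06, adjusted p = 0.664 with an estimated correlation). Sftpc (3.07 ± 0.79) was higher too, at 607.1 RPKM in 1 tumour and 0 to 20.9 in the other 5. Gjb1 (-1.61 ± 0.39), Cyp2f2 (-1.57 ± 0.40), Ptges (-1.57 ± 0.32), Scand1 (-1.58 ± 0.36) and H2-Q10 (-1.70 ± 0.40) were lower. Among 6 against 14 animals limma called 755 of 11465 genes, 320 higher (56 at least 2-fold) and 435 lower (30), the genes named here with adjusted p up to 0.0354. After rescaling, 433 were higher and 323 lower.

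With the same reservation for both genes, BL10 tumours exceeded FVB in H2-Aa (3.21 ± 0.56, 69.5 against 10.2 RPKM) and H2-Eb1 (4.34 ± 0.15, 27.9 against 0.415 RPKM). The fibrinogen chains Fgb (2.93 ± 0.41) and Fgg (2.86 ± 0.74) and Prol1 (2.84 ± 0.53) were higher. Among 7 MHC class II genes 5 were higher, 0 lower and 2 not called (6 higher adjusted over the list alone, adjusted p = 3.16e-07, adjusted p = 0.259 with an estimated correlation). Of 3 hepatocyte genes 2 were higher, 0 lower and 1 not called (2 higher adjusted over the list alone, adjusted p = 0.0386, adjusted p = 0.259 with an estimated correlation). The amino acid transporters Slc7a5 (-1.38 ± 0.29) and Slc38a6 (-1.56 ± 0.26), the protease Tmprss4 (-1.40 ± 0.39), Cyp2f2 (-1.38 ± 0.40) and Cplx2 (-1.41 ± 0.35) were lower. Within 6 against 14 animals limma called 1076 of 11489 genes, 630 higher (102 at least 2-fold) and 446 lower (29), the genes named here with adjusted p up to 0.0348.

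CAST tumours were low in interferon-stimulated genes: Rsad2 (-1.69 ± 0.55, 2.18 against 14.2 RPKM), Oasl2 (-1.77 ± 0.52, 5.28 against 24.4 RPKM), Oas2 (-1.81 ± 0.48) and Iigp1 (-2.22 ± 0.44). The 21 interferon-stimulated genes split into 0 higher, 9 lower and 12 not called (16 lower and 1 higher adjusted over the list alone, adjusted p = 7.88e-07, adjusted p = 0.933 with an estimated correlation). The RNA editing gene Adarb2 (-1.69 ± 0.35) was lower too. Saa3 (2.94 ± 0.69), the lysozyme gene Lyz1 (2.68 ± 0.67), Amtn (4.2 ± 0.84) and, uncertain between strains, H2-Eb1 (3.0 ± 0.20) and Npm3-ps1 (3.64 ± 0.14) were higher. Using 7 against 14 animals, limma called 1501 of 11458 genes, 851 higher (134 at least 2-fold) and 650 lower (43), the genes named here with adjusted p up to 0.0442. Variants against the reference genome were not separated from expression in this strain or in MOLF, and 5 of 7 CAST and 6 of 8 MOLF tumours were of a series without FVB tumours.

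MOLF tumours had the same direction for interferon-stimulated genes, with Ifit3 (-2.13 ± 0.52, 2.27 against 17.8 RPKM) and Oas1a (-2.19 ± 0.52, 7.15 against 35.6 RPKM) lower. Among 21 interferon-stimulated genes 0 were higher, 17 lower and 4 not called (19 lower adjusted over the list alone, adjusted p = 6.42e-04, adjusted p = 0.842 with an estimated correlation). Cmah (-2.10 ± 0.42) and Cldn10 (-2.13 ± 0.43) were lower as well. Saa3 (4.71 ± 0.83), Lyz1 (3.89 ± 0.65) and the milk genes Csn1s1 (3.55 ± 0.89) and Glycam1 (3.80 ± 0.87) were higher. Out of 8 against 14 animals limma called 4105 of 11341 genes, 1367 higher (197 at least 2-fold) and 2738 lower (199), the genes named here with adjusted p up to 0.00398. After rescaling, 1906 were higher and 2068 lower.

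Liver metastases of M6 after injection into the heart were rich in hepatocyte RNA when set against primary tumours of other animals, injected into the mammary gland. Alb (12.55 ± 0.33, 7514 against 0.0327 RPKM) and Serpina1c (11.03 ± 0.36, 3017 against 0.153 RPKM) rose with major urinary protein genes such as Mup2 (11.59 ± 0.85), a family with near-identical copies. Of 16 hepatocyte genes 16 were higher, 0 lower and 0 not called (16 higher adjusted over the list alone, adjusted p = 1.80e-37, adjusted p = 0.055 with an estimated correlation), with Apoa2 (10.28 ± 0.20) and Ttr (9.91 ± 0.20). Crabp1 (-3.33 ± 0.54), Lrrc15 (-3.62 ± 0.37), Cxcl14 (-3.70 ± 0.55), Ccl8 (-3.96 ± 0.25) and Mfap5 (-4.08 ± 0.31) fell. The 20 fibroblast matrix genes split into 1 higher, 15 lower and 4 not called (16 lower and 2 higher adjusted over the list alone, adjusted p = 0.0181, adjusted p = 0.905 with an estimated correlation), with Col12a1 (-2.79 ± 0.31) and Loxl1 (-1.91 ± 0.26). Comparing 7 with 6 animals, limma called 4760 of 11420 genes, 1280 higher (913 at least 2-fold) and 3480 lower (731), the genes named here with adjusted p up to 3.15e-04. Rescaled, 1951 were higher and 1593 lower, and the median over all genes moved from -0.34 to -0.02. Route, library series and strain tag went with the tissue.

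Within 3 animals, liver and lung metastases of M6 differed in the genes of their organ. Alb (10.03 ± 0.24, 2839 against 2.14 RPKM), Ahsg (9.09 ± 0.27, 987 against 0.966 RPKM) and Apoa1 (8.83 ± 0.35) were higher in liver, Sftpc (-10.78 ± 0.29), Sftpb (-7.47 ± 0.30), Sftpa1 (-7.11 ± 0.22) and Lyz1 (-7.85 ± 0.48) in lung. Among 16 hepatocyte genes 16 were higher, 0 lower and 0 not called (16 higher adjusted over the list alone, adjusted p = 2.60e-36, adjusted p = 0.497 with an estimated correlation). Of 9 alveolar type 2 genes 0 were higher, 8 lower and 1 not called (8 lower adjusted over the list alone, adjusted p = 5.80e-13, adjusted p = 0.497 with an estimated correlation). From these 3 pairs limma called 967 of 11540 genes, 483 higher (476 at least 2-fold) and 484 lower (463), the genes named here with adjusted p up to 5.28e-04. After rescaling, 518 were higher and 325 lower, and the median over all genes moved from -0.10 to 0.05.

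Resected Met1 primary tumours were compared with tumours taken at the end from the same 4 animals. Bnip3 (1.48 ± 0.51), a hypoxia gene, and Krt7 (1.80 ± 0.78) were not called (both adjusted p = 0.541). The 19 hypoxia and glycolysis genes split into 0 higher, 0 lower and 19 not called (0 higher adjusted over the list alone, adjusted p = 1.25e-06, adjusted p = 0.819 with an estimated correlation). Among 7 MHC class II genes 0 were higher, 0 lower and 7 not called (6 lower adjusted over the list alone, adjusted p = 4.16e-04, adjusted p = 0.819 with an estimated correlation), with Ciita (-1.35 ± 0.52) and H2-Eb1 (-1.56 ± 0.64, both adjusted p = 0.541). Over the 7 final tumours Cd79b of B cells reached 292.6 RPKM and Krt8 fell to 44.39. Resected tumours had at most 0.2086 and at least 275.2. The lower MHC class II, and Cd74 in Met1 above, may rest on 1 tumour. In those 4 pairs limma called 0 of 10856 genes, with 904 at an unadjusted p under 0.05 where 543 were expected. Rescaling moved the median over all genes from -0.10 to 0.03.

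Tumours differed from the same 7 lines in culture in the genes of host cell types. Lyz2 (8.71 ± 0.30, 1140 against 1.60 RPKM), C1qa (7.19 ± 0.23, 186 against 0.157 RPKM) and Ctss (7.05 ± 0.21) of macrophages, Apoe (6.93 ± 0.25) and the haemoglobin gene Hba-a2 (6.93 ± 0.37) were higher in tumours. Of 12 macrophage genes 12 were higher, 0 lower and 0 not called (12 higher adjusted over the list alone, adjusted p = 2.01e-14, adjusted p = 0.17 with an estimated correlation), with C1qb (6.76 ± 0.23). Cultured cells held more Asns (-2.29 ± 0.31), which makes asparagine, Gpt2 (-2.01 ± 0.32), Cxcl1 (-2.05 ± 0.37), Adh7 (-2.92 ± 0.18) and Rnd1 (-1.91 ± 0.28). The 10 stress response genes split into 2 higher, 6 lower and 2 not called (6 lower and 2 higher adjusted over the list alone, adjusted p = 0.0184, adjusted p = 0.53 with an estimated correlation), with Sesn2 (-1.36 ± 0.21), Chac1 (-2.65 ± 0.46) and Trib3 (-2.15 ± 0.44). Pairing the means of each line, limma called 2643 of 11214 genes, 1584 higher (929 at least 2-fold) and 1059 lower (111), the genes named here with adjusted p up to 0.00779.

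Tumour-adjacent lung of PyMT mice in FVB held more of the heat-shock genes Hspa1a (2.39 ± 0.54, 77.0 against 12.8 RPKM), Hspa1b (2.42 ± 0.50, 101 against 17.1 RPKM) and Dnajb1 (1.46 ± 0.31), and of Fos (1.94 ± 0.53) and Sln (3.43 ± 0.76), than healthy lung. Among 10 NRF2 target genes 3 were higher, 0 lower and 7 not called (3 higher adjusted over the list alone, adjusted p = 0.00279, adjusted p = 0.807 with an estimated correlation), with Hmox1 (1.41 ± 0.27) and Slc7a11 (0.62 ± 0.13). Gzma (-1.73 ± 0.32) of cytotoxic lymphocytes, Ifi204 (-2.90 ± 0.13), Hbb-b1 (-1.99 ± 0.30) and Shfm1 (-1.76 ± 0.13) were lower. In 5 against 4 animals limma called 1639 of 12054 genes, 433 higher (13 at least 2-fold) and 1206 lower (93), the genes named here with adjusted p up to 0.0417. After rescaling, 786 were higher and 929 lower. The 5 adjacent lungs came from another library series than the 4 healthy ones, so series and tissue were confounded.

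Tumour-adjacent liver of injected mice had more of the metal-binding Mt1 (2.10 ± 0.43, 704 against 149 RPKM), Fgl1 (1.68 ± 0.38, 500.4 against 136 RPKM), Egfr (1.61 ± 0.29), Actb (1.58 ± 0.27) and the lung transcription factor Nkx2-1 (2.45 ± 0.36) than healthy liver. Leap2 (-1.24 ± 0.25), Cyp3a16 (-1.43 ± 0.32), Cyp2c69 (-1.57 ± 0.27), Serpina3i (-1.57 ± 0.28) and Lars2 (-1.96 ± 0.34) were lower. Of 8 against 4 animals limma called 99 of 8713 genes, 63 higher (29 at least 2-fold) and 36 lower (13), the genes named here with adjusted p up to 0.0432. Rescaled, 723 were higher and 477 lower. Library series went with the group here too.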

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

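The tests of lung admixture, dilution, scaling, exchanged libraries and other splits of the samples reported here and below were chosen after the results were seen. In groups of 4 to 10 samples the highest or lowest sample was compared with the others by Dixon's test for sequencing depth, Sftpc, S100a9 and Col1a1. Chance alone marks about 1 in 20 groups, or 3.7 of the 74 tested, and 11 were found. In depth (counted megareads) a D2A1 tumour stood apart at 54.91 (nearest 33.87), an EMT6 tumour at 37.92 (31.82), an Mvt1 metastasis at 24.51 (26.87) and a BL6 tumour at 49.25 (30.41). Sftpc on the log2 scale stood apart in single primary tumours of 6DT1 at 0.62 (0.32), Met1 at 1.69 (0.46) and BL10 at 2.47 (0.80). S100a9 was low in the metastases of 1 Met1 animal, at 2.32 (6.96). Col1a1 was low in 1 BL6 tumour at 2.06 (4.24) and 1 CAST tumour at 3.16 (4.78), and high in 1 MOLF tumour at 7.59 (5.27).

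Allografts and transgenic models differed in the step from tumour to metastasis, with 76 genes called by an interaction test. That number was 17 after subtraction of the lung share, 8 without the filter on low values, 466 without Met1 and 23 to 58 without 1 other model.

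Libraries outside the comparisons held signals above their controls. Lung metastases labelled M6 after injection into the heart, both from mouse1274, had Alb at 3201 and 3049 RPKM against at most 0.278 in healthy lung, with Sftpc at 0 and 0.0436, so their tissue label is in doubt. Sftpc reached 71550 in the only Met1 metastasis after tail vein injection, against at most 13720 in healthy lung, while its Csn3 was at 0.0605 against 1219 to 6587 in orthotopic Met1 metastases, so its label is in doubt too. Brain metastases had the neuronal Snap25 at 944.3 in M6 and 1816 in Met1 (at most 0.2504 and 0.2684 in their primary tumours), but Krt8 at 1.06 and 3.94. A spleen metastasis of Met1 had Krt8 at 0.340, against 257 and 423 in the other 2, which leaves open whether it holds tumour. Krt8 exceeded the highest healthy liver (38.4) in liver metastases of Met1 at 159.8, 209.2 and 106 and of 6DT1 at 65.27 and 131.4. Erbb2, the gene that encodes Neu, was at 305.8, 289.1, 297.1 and 300 in metastases of MMTV-Neu mice against at most 6.15 in healthy lung. Its level was 48.01 and 274.2 in their primary tumours, against at most 15.6 in PyMT tumours of FVB mice.

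Neutrophil genes were higher in metastases by a median of 1.73 ± 0.62 (log2, mean and SD over 10 models). A mixture of primary tumour and healthy lung at the estimated share left 1.59 ± 0.66 unexplained, above 0 in 10 of 10 models (exact sign-flip p = 9.77e-04, the smallest it can give). With tumour-adjacent lung in the mixture 1.6 was left. Admixed RNA of those FVB lungs thus did not account for the pattern. Neutrophil entry into metastases may account for it, while lung of other models, retained blood and collection time stay open, untested. Of red cell genes Hba-a2 (1.86) and Hbb-b1 (1.85) were called higher in the shared comparison too, but in PyMT in FVB they were at -0.65 ± 0.40 and -0.72 ± 0.44, not called, with S100a9 at 3.22.

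Fibroblast matrix genes were lower by -0.98 ± 0.49 over the same models. Dilution by lung RNA was excluded as the whole cause, since -1.01 ± 0.48 was left relative to the mixture, below 0 in 10 of 10 models (exact sign-flip p = 9.77e-04). Scaling was excluded too, with 16 of 20 members still called lower after rescaling to the median ratio. A smaller share of fibroblasts in metastases may be the source, and size and age of the lesions were not tested.

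A BL6 primary tumour, of mouse9873, had Sftpc at 607.1 RPKM (0 to 20.9 in the other 5), and 1 BL6 metastasis, of mouse9783, had 0.3636 (170 to 8943 in the other 8). If the 2 libraries had been exchanged, most type 2 genes of the metastasis would lie at or below the highest other tumour, and 9 of 9 did, while 6 of 9 of the tumour lay at or above the lowest other metastasis. Among BL6 animals the metastasis had the highest Col1a1 and Lum of its group (48.95 and 20.87), the tumour the lowest (3.177 and 0.2767). These argue against lung RNA in the tumour as the whole cause. Column names give both libraries the number of mouse9783, though titles differ. An exchange is thus a candidate, and no library was reassigned. Neither entered the paired test of BL6, but the tumour entered the comparison with FVB, which had 496 calls without it.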

How the results depend on the processing

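Leaving out whole models or lines, pairing BL6 by deposited column name, the mean in place of the median for lung cell shares, and leaving out 2 BL6 animals or the animal with surfactant above healthy lung were tests chosen after results were seen. Of 175 counts of calls under other settings 131 lay within 1.5 times the reported count and 44 did not. With 1 animal left out 455 of 539 did and 84 did not. Among 9736 refits of named genes that were called 9162 kept their call and direction, 572 lost the call and 2 were reversed, and 14 of 274 of genes not called gained it. Those 2 were Ramp2 (-1.66, adjusted p = 6.18e-04) and Esam (-0.87, adjusted p = 0.00337) of the shared comparison with the lung share subtracted, and the cause was not tested. Of called genes, the KS series alone kept 30 of 64, no filter 290 of 349 and 1 animal left out 7205 of 7577. Without animals titled lung met, 2 of 5 stayed in Met1 and 5 of 10 in MOLF. None of the 52 refits without mouse9716 changed a call.

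Subtracting the lung share left 657 calls for 4T1, 154 for M6, 54 for PyMT in FVB, 26 for BL6 and 17 for the interaction of allografts with transgenic models. By route it left 279 for 4T1, 284 for Mvt1 and 379 for 6DT1. Liver metastases of M6 kept a count of 391 against primary tumours with the liver share subtracted, and 142 against lung metastases with both shares subtracted. Of the named called genes 23 of 167 lost their call with the lung share subtracted.

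Without the filter on low values limma called 8 genes for Met1, 315 for PyMT in FVB, 2 for BL6, 11 for BL10, 8 for the interaction of allografts with transgenic models, 1 for the interaction of Met1 with PyMT in FVB, 500 for 6DT1 by route, 234 for liver against lung metastases and 36 for adjacent liver. Rescaling to the median ratio gave 42 for the first interaction, 160 for Mvt1 by route and 1200 for adjacent liver. The KS series of libraries alone gave 13 for PyMT in FVB and 16 for BL10, and the RNA series alone 13 for PyMT in FVB. For tumours against FVB the KS series gave 1270 for BL6, 1811 for BL10, 445 for CAST and 1244 for MOLF. MOLF had 76 without the animals titled lung met.

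Without the replicate block the counts were 57 for Met1, 224 for PyMT in FVB, 545 for BL10 and, with 2 animals without a partner brought in, 0 for BL6 (limma, 733 at an unadjusted p under 0.05), but 65 for BL6 without them. The block moved no other count by over 1.5 times, and of the named called genes 88 of 107 kept their call without it and 19 lost it. Paired by deposited column name BL6 had 0 (848 at an unadjusted p under 0.05). The estimated correlation between genes kept 6 of 397 gene list calls, namely type 2 (adjusted p = 0.0194), type 1 (0.0194) and club cell genes (0.0194) in PyMT in FVB and the same lists in MOLF (0.00575, 0.00726 and 0.00818).

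With the 5 injected lines and PyMT in FVB alone the shared count was 1465. The interaction of allografts with transgenic models had 24 without 4T1, 25 without 6DT1, 23 without Mvt1, 466 without Met1, 31 without BL6, 31 without BL10, 30 without CAST and 38 without MOLF. The nearest profile was of the own model for 75.7% to 82.9% of animals over the settings, and of the own driver for 95.7% to 98.6%.

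Single animals, each left out alone, moved counts of metastases against primary tumours. 4T1 (1363 calls) had 509, 730, 884, 491 and 597 without mouse1, mouse10, mouse12, mouse2 and mouse9, and at most 1409. 6DT1 (3828 calls) had 2302 and 2198 without mouse2 and mouse3, and at most 5341. Mvt1 (3172 calls) had 2023, 1514 and 1698 without mouse3, mouse4 and mouse6, and at most 4260. Met1 (35 calls) had 8, 12 and 9 without mouse10, mouse13 and mouse3, and at most 45. M6 (529 calls) had 292, 247, 295 and 212 without mouse823, mouse873, mouse874 and mouse878, and at most 581. PyMT in FVB (141 calls) had 73, 74, 73, 81, 66 and 58 without mouse9470, mouse956CH, mouse9703, mouse9715, mouse9738 and mouse977CH, and at most 179. BL6 (73 calls) had 203, 41, 35 and 25 without mouse9777, mouse9781, mouse9791 and mouse9792. BL10 (287 calls) had 859, 16, 169, 44 and 33 without mouse9786, mouse9788, mouse9891, mouse9895 and mouse9896. CAST (505 calls) had 172, 122, 207, 127, 905 and 290 without mouse10055, mouse10075, mouse10077, mouse10131, mouse9801 and mouse9802. MOLF ran from 81 to 140, the shared comparison from 3062 to 3554 and the interaction of allografts with transgenic models from 51 to 108. The interaction of Met1 with PyMT in FVB had 0 to 1, with 1 without Met1 mouse10 and mouse9 (limma, 686 at an unadjusted p under 0.05 with all animals).

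By route of injection 4T1 (649 calls) had 269, 235 and 1521 without orthotopic mouse10, mouse12 and mouse9 and 187, 295, 161, 287 and 288 without tail vein mouse1, mouse4, mouse6, mouse8 and mouse9. Mvt1 (470 calls) had 306, 192, 119 and 292 without orthotopic mouse1, mouse2, mouse4 and mouse5 and 304, 222, 257, 176 and 169 without tail vein mouse1, mouse2, mouse3, mouse4 and mouse7, and at most 704. 6DT1 (1187 calls) had 2025, 2879, 161, 279 and 282 without orthotopic mouse0, mouse1, mouse2, mouse3 and mouse5 and 227 and 5 without tail vein mouse9540 and mouse9543, where the lone tail vein animal left is assumed to vary like the others. BL6 tumours against FVB (755 calls) had 451, 365 and 496 without mouse9777, mouse9792 and mouse9873, and at most 958. BL10 tumours (1076 calls) had 703, 491 and 440 without mouse9839, mouse9895 and mouse9896, and at most 1545. CAST tumours (1501 calls) had 924 without mouse10131, and at most 1886. Liver against lung metastases of M6 (967 calls) had 400 without mouse878, and at most 1014. Resected against final Met1 tumours (0 calls by limma, 904 genes at an unadjusted p under 0.05) had 1 and 27 without mouse1 and mouse3, with 0 as the lowest. Adjacent lung (1639 calls) had 973, 1074 and 861 without adjacent mouse9200m, mouse9201m and mouse9469f and 934 and 760 without healthy PF1 and PF2, and at most 1735. Adjacent liver (99 calls) had 243 without adjacent mouse1274 and 31, 31, 45 and 186 without healthy mouse10272, mouse10273, mouse10274 and mouse10484. Ranges within 1.5 times were 6794 to 7177 for Myc, 4831 to 6142 for C3Tag and 2939 to 3904 for Met1 tumours against PyMT, 6334 to 6883 for 4T1 and 6942 to 7454 for 4T07 against 67NR, 4290 to 5053 for 4T1 against 4T07, 3153 to 4493 for MOLF against FVB, 3826 to 4900 for liver metastases against tumours and 2513 to 2766 for tumours against cells.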

Other observations

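MMTV-Neu mice, among them mouse472CH with PyMT-Neu in its titles, had milk protein RNA in both tissues. Csn3 was at 18760, 25260, 8878 and 10520 RPKM in 4 metastasis libraries of 2 animals and at 12560 and 9743 in their primary tumours, and Lalba at 812 to 1140 and at 208 and 1070.

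Primary tumours of 7 further injected lines, 4 libraries of each, spanned a range of keratin. Column names give the 4 TSAE1 libraries 1 animal number, so their SD need not be between animals. Krt8 averaged 777 ± 34.3 RPKM in TSAE1, 718 ± 162 in HRM1, 556 ± 95.0 in R3T, 287 ± 49.9 in F311, 208 ± 39.5 in EMT6, 70.4 ± 16.6 in E0771 and 37.2 ± 5.60 in D2A1. Epcam stood at 122 ± 19.2 in HRM1 but at 1.01 ± 0.44 in E0771 and 0.698 ± 0.41 in D2A1. E0771 tumours stood out with Gpnmb at 56.4 ± 8.88 RPKM, against 0.268 to 1.85 in the other 6.

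RNA of lung cell types was not present in metastases in equal proportion. Relative to healthy lung, type 2 cell genes stood at 18.3 ± 9.71% (mean and SD over 10 models of the median within a model), above type 1 (8.24%), capillary (3.55%), club (1.44%) and ciliated cell genes (0.894%) in 10 of 10 models each (exact p = 0.00195, adjusted p = 0.00244). Against alveolar macrophage genes, at 17.4%, they were higher in 6 of 10 (exact p = 0.904). With the mean within a model the shares were 28.1% for type 2, 9.14% for type 1, 5.01% for capillary, 2.33% for club and 2.49% for ciliated cell genes, again 10 of 10, and 23.7% for alveolar macrophage genes (4 of 10, exact p = 0.514). The type 2 mean was 67.3% in PyMT in FVB, where the median was 13.7%.

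Each count of calls between groups of at least 3 was set against other splits of the same samples, which leaves out the routes in 6DT1 with 2 tail vein animals. For 6 pairs, 1 of 32 splits gave as many calls, the real one, for 4T1 (1363, highest other 0), 6DT1 (3828, 1827), Mvt1 (3172, 400), Met1 (35, 1), M6 (529, 2) and BL10 (287, 1). It was 1 of 64 for CAST (505, 27) and for tumours against cells (2643, 43). Likewise 1 of 100 excluded chance for PyMT in FVB (141, 1), MOLF (121, 5), the shared comparison (3411, 0), the interaction of allografts with transgenic models (76, 6), the routes in 4T1 (649, 58) and Mvt1 (470, 5), tumours of Myc (7132, 16), C3Tag (6017, 49) and Met1 (3528, 48) against PyMT, 4T1 (6672, 2) and 4T07 (7181, 4278) against 67NR, 4T1 against 4T07 (4792, 1252), tumours of BL6 (755, 54), BL10 (1076, 0), CAST (1501, 212) and MOLF (4105, 1551) against FVB, liver metastases against tumours (4760, 9) and adjacent lung (1639, 775). Adjacent liver had 4 of 100 splits as large, a share under 0.05, but another split called 5660 against its 99, which points to a structure of these samples other than tumour. For the interaction of Met1 with PyMT in FVB 100 of 100 splits gave at least its 0 calls (limma, 686 genes at an unadjusted p under 0.05), as any split must, so the comparison tells nothing about chance. The splits were too few for a share under 0.05 in BL6 (1 of 16, 73, highest other 0), liver against lung metastases (1 of 4, 967, 0) and resected against final tumours (8 of 8, 0 by limma with 904 at an unadjusted p under 0.05, 81).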
